A study of Homo sapiens with 12 samples.

How the data were processed

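Polyadenylated RNA was sequenced from TE10 and Kyse410 cells carrying a UHRF1 shRNA or a scramble control, with 3 libraries in each of 4 groups. The deposited files hold raw counts, 1 file per library, as whole numbers of reads per gene followed by HTSeq's counters of reads given to no gene. The authors' notes name bcl2fastq 2.19, HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 and the genome build GRCh37.p13, without their order or settings. The annotation release and the strand setting are not given in the sources used here. Of 57820 gene identifiers, 52338 were matched to symbols in a GENCODE annotation, and these held 99.02% of the gene reads. The annotation at hand is of another build, so no positions are given. UHRF1 was named by hand from its identifier, ENSG00000034063, which the annotation did not match.

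Gene reads per library ranged from 7857662 to 12005229, of 19346007 to 30727953 reads in all. Reads that HTSeq gave to no feature took 42.88 to 44.66% of each library. With the strand setting unknown, such reads need not lie outside annotated genes. Antisense genes that overlap coding exons on at least 90% of their bases held 1.79 times the reads per base of their partner (median of 251 pairs), against 0.009 where no base overlaps (850 pairs). Reads of an antisense gene and of the coding gene it overlaps therefore cannot be told apart in these counts. Between replicates of a group the chi-square per degree of freedom, over genes with at least 20 counts, was 1.57 to 2.92, where counting error alone gives about 1. Intervals from read counts cover counting error only.

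The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the groups as design, which left 16060, and scaled by TMM. One quasi-likelihood fit held all 12 libraries with a mean per group and 8 residual degrees of freedom. The contrasts were shRNA minus scramble in each line, the difference of these between lines (Kyse410 minus TE10) and Kyse410 minus TE10 among scramble controls. P-values were adjusted by Benjamini-Hochberg over all genes tested and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with their standard errors (SE), and levels are TMM-scaled CPM (reads per gene relative to the scaled library total) with the SD of 3 libraries. Overlaps were tested with one-sided Fisher's exact tests. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.

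The comparisons, tests, gene lists and rule for named genes were set before the data were examined. The rule took, for each knockdown comparison, the 7 largest rises and 7 largest falls among called genes with a symbol, a mean of at least 5 CPM in the line and no overlap between the groups' libraries. It added the 3 members with the smallest adjusted p in the direction of the call from each called list, and UHRF1, CDH1, VIM, CDH2, FN1, SNAI1, SNAI2, ZEB1, AKT1, AKT2, MMP2, MMP9 and DNMT1 whatever their values. It took the 5 largest differences each way between the lines among called genes with a mean of at least 5 CPM over the 12 libraries. It took the 6 largest shared changes each way, ranked by the smaller change, with at least 5 CPM in each line. Between scramble controls it took the 4 largest differences each way with at least 5 CPM over these libraries, and CDH1, VIM, CDH2, ZEB1 and UHRF1. Pseudogenes, read-through loci and clone names were passed over. Some genes that the rule takes are not reported here.

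The 30 lists held 889 members, of which 29 were not matched. They cover DNA methylation, mesenchymal and epithelial state, Akt pathway components, FOXO targets, DNA replication, mitosis, p53 targets, interferon response, germline genes, imprinted genes, matrix proteases, collagens with laminins and integrins, squamous differentiation and basal squamous identity. The others are hypoxia and glycolysis, the unfolded protein response, ATF4 targets, cholesterol, ribosomal proteins, ribosome biogenesis, TGF-beta targets, NF-kB targets and cytokines, immediate early genes, Wnt and Notch targets, apoptosis regulators, mitochondrially encoded transcripts, replication histones, blood cells, and fibroblasts with endothelial cells. Each was counted over all genes and adjusted over the list alone. Those with at least 5 tested members, 28 in each comparison, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg within a comparison. Calls were repeated with a correlation estimated from the data and with fry.

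The pipeline was tested on simulated data with 50 genes changed at each size. It called 88% of genes changed 2-fold in TE10, 82% in Kyse410 and 62% for the difference between lines, and 64%, 70% and 44% of genes changed 1.5-fold. Of genes changed 1.25-fold it called 32%, 46% and 16%. False calls made up 4.9%, 5.8% and 2.6% of the calls. Far fewer genes changed in the simulation than were called in the real data, so these shares need not hold there.

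The alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter at 1 CPM in 6 libraries, each line or the scramble libraries alone, the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Leaving out mitochondrial transcripts before scaling was added after the data were seen. The 47 identifiers of the Y copy of the pseudoautosomal regions were left as deposited, and splicing was not analysed here.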

Results

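RNA sequencing was carried out on TE10 and Kyse410, established human cell lines of esophageal squamous cell carcinoma, after stable infection with a construct expressing a short hairpin RNA (shRNA) against UHRF1 or with a scramble control. UHRF1 is a ubiquitin ligase that binds hemimethylated DNA and guides the methyltransferase DNMT1 to newly replicated DNA. Each of the 4 groups had 3 libraries of polyadenylated RNA, 12 in all. The libraries held 7857662 to 12005229 reads assigned to genes. By group of 3 libraries the gene reads ranged from 7857662 to 8194914 in TE10 with the shRNA, from 8053970 to 9809414 in TE10 with the scramble, from 8794930 to 11597426 in Kyse410 with the shRNA and from 9512502 to 12005229 in Kyse410 with the scramble. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. In a principal component analysis of log2 CPM the first component, with 73.6% of the variance, separated the lines. The second, with 12.3%, separated shRNA from scramble libraries in both lines.

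UHRF1 itself was measured first, as a check of the labels. In TE10 the transcript (ENSG00000034063) lay at 85.9 ± 3.5 CPM with the shRNA and at 178.5 ± 5.3 CPM with the scramble (mean ± SD, n = 3 each). This left 48.1% of the control level (95% confidence interval 44.2 to 52.3%), a log2 fold change of −1.06 ± 0.053 (SE; edgeR quasi-likelihood adjusted p = 3.22e-23). In Kyse410 it lay at 42.5 ± 0.9 CPM with the shRNA and at 99.1 ± 3.5 CPM with the scramble. There 42.9% of the control level remained (39.1 to 47%), a log2 fold change of −1.22 ± 0.057 (SE; edgeR adjusted p = 1.62e-24). In both lines the 3 shRNA libraries all lay below the 3 scramble libraries. The response of UHRF1 did not pass the test of a difference between the lines (log2 difference −0.16 ± 0.0785, edgeR adjusted p = 0.093).

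**Figure D1:**
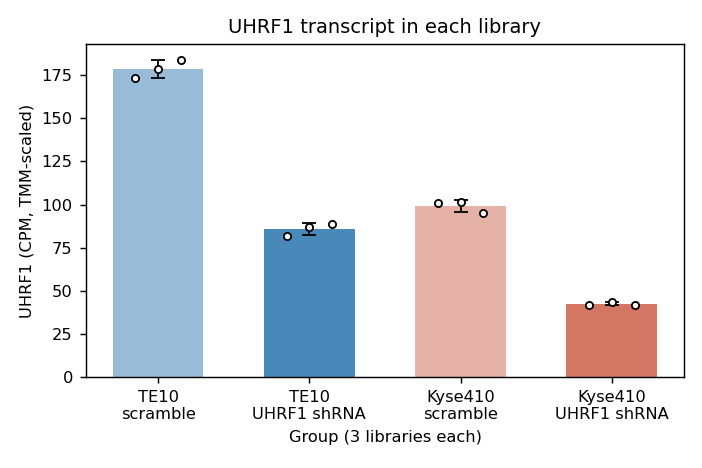
UHRF1 transcript in TMM-scaled CPM (vertical axis) for the 4 groups of 3 libraries. Bars are means, error bars SDs and circles single libraries, and the shRNA groups sit at 48.1% of the scramble level in TE10 and 42.9% in Kyse410.

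The TE10 libraries with the shRNA were compared with their scramble controls to find the transcripts that moved with UHRF1, with particular regard to the epithelial-mesenchymal transition (EMT) and Akt signalling, which the study's design names. TE10 cells with the shRNA had less mesenchymal and matrix RNA and more epithelial RNA. SPARC, a secreted collagen-binding matrix protein, fell by 3.83 on the log2 scale (SE 0.0949), and the tenascin TNC fell by 2.37 (SE 0.066). CDH1, which encodes E-cadherin, rose by 1.20 (SE 0.0565), and the keratin gene KRT19 rose by 1.07 (SE 0.041). Interferon-induced and cholesterol synthesis genes were lower as well, among them IFIT2 at −1.56 (SE 0.0506) and INSIG1, which holds back sterol-responsive transcription factors, at −1.63 (SE 0.0882). Each of these 6 changes passed the edgeR test at the adjusted threshold of 0.05.

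Of 16060 genes tested in TE10, 6231 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3019 higher and 3212 lower with the shRNA. Without shRNA replicate 1 the balance turned, with 3075 higher and 2564 lower. Most of these changes were small, with a median absolute log2 fold change of 0.42. Those of at least 2-fold numbered 971, of which 343 were higher and 628 lower. The largest rises among expressed genes were in ZNF114 (log2 4.07 ± 0.217), the germ cell alkaline phosphatase gene ALPG (3.90 ± 0.108), MPPED1 (3.81 ± 0.197), NCCRP1 (3.65 ± 0.22), the ganglioside synthesis gene B4GALNT1 (3.47 ± 0.18), the pluripotency-associated zinc finger gene ZFP42 (3.19 ± 0.18) and FRMD3 (2.84 ± 0.131). ALPG shares near-identical sequence with ALPP, so its level is uncertain. ALPP, named here after its values were seen, rose as well, from 135.6 ± 3.87 to 560.1 ± 0.284 CPM. At a mean of at least 5 CPM in the line, the largest falls were in the collagen gene COL5A3 (−4.28 ± 0.258), SPARC, the focal adhesion gene TNS1 (−3.67 ± 0.169), the microtubule-associated gene MAP1B (−3.46 ± 0.188), the basal keratin gene KRT5 (−3.06 ± 0.117), EDIL3 (−2.85 ± 0.179) and the nicotinamide methyltransferase gene NNMT (−2.62 ± 0.116).

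Among the 17 mesenchymal genes tested in TE10, 14 fell and 0 rose, with the same counts adjusted over the list alone, and the list had a median log2 fold change of −0.97 (camera adjusted p = 2.44e-22). Vimentin (VIM) fell from 844.7 ± 9.0 to 355.5 ± 5.7 CPM, a 2.38-fold fall. N-cadherin (CDH2) fell by 0.85, fibronectin (FN1) by 0.97, SNAI2 by 0.54 and ZEB1 by 1.05 on the log2 scale. SNAI1 was at 0.17 ± 0.116 and did not pass (edgeR adjusted p = 0.253). Of 22 epithelial genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 1.34e-15). A further example besides CDH1 and KRT19 was the membrane serine protease gene ST14 (1.39 ± 0.0649).

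The lists of matrix and basal cell genes were also called downward in TE10, each with members that rose. Of 31 collagen, laminin and integrin genes, 23 fell and 6 rose, likewise adjusted over the list alone (camera adjusted p = 7.46e-17), with COL5A1 at −1.11 ± 0.0366, ITGB4 at −0.97 ± 0.0351 and COL7A1 at −0.86 ± 0.0419. Of 27 matrix protease and plasminogen system genes, 13 fell and 7 rose (13 and 8 adjusted over the list alone), and camera gave an adjusted p of 2.46e-07. CTSB, which encodes cathepsin B, was at −1.15 ± 0.0353, SERPINE2 at −1.28 ± 0.0461 and ADAM12 at −1.57 ± 0.084. MMP2 and MMP9 had at most 9 and 7 reads in any library and were not tested. Of 22 basal squamous genes, 12 fell and 6 rose (the same adjusted over the list alone; camera adjusted p = 2.13e-05), with KRT14 at −2.28 ± 0.115 and DST at −0.74 ± 0.044 beside KRT5. TGF-beta targets had 11 falls and 6 rises among 25 (the same adjusted over the list alone; camera adjusted p = 0.00078), with BHLHE40 at −1.21 ± 0.0452, TGFBI at −1.15 ± 0.0438 and THBS1 at −0.99 ± 0.0557. That call was lost with an estimated correlation, at an adjusted p = 0.0666.

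Of 39 interferon response genes in TE10, 31 fell and 1 rose (32 and 1 adjusted over the list alone), with a median of −0.69 (camera adjusted p = 5.88e-22). IFIT1 was at −1.45 ± 0.0596 and IFIT3 at −1.28 ± 0.0593. NF-kB targets and cytokine genes had 14 falls and 3 rises among 26, the same adjusted over the list alone (camera adjusted p = 0.0016). Complement C3 fell by 1.90 (SE 0.0816). IL33 had 116 reads in the scramble libraries and 1 read in the shRNA libraries, a ratio of 105 with a 95% counting interval of 18.5 to 4190, and CXCL11 fell by 3.93 from a low level. Cholesterol synthesis and uptake genes had 22 falls and 0 rises among 25, with the same counts adjusted over the list alone and a median of −0.55 (camera adjusted p = 3.51e-21). FDFT1, the squalene synthase gene, was at −0.96 ± 0.0445 and HMGCS1 at −0.92 ± 0.0434. Hypoxia and glycolysis genes had 17 falls and 4 rises among 30 (20 and 4 adjusted over the list alone; camera adjusted p = 2.22e-06), led by the glucose transporter gene SLC2A3 (−2.15 ± 0.0668), NDRG1 (−1.18 ± 0.0472) and DDIT4 (−0.76 ± 0.0482). The call of this list gave an adjusted p = 0.0534 with an estimated correlation.

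Smaller shifts upward were seen in genes of protein synthesis and folding in TE10. Ribosome biogenesis genes had 19 rises and 4 falls among 36 (22 and 4 adjusted over the list alone; camera adjusted p = 0.0129), with ODC1 at 0.41 ± 0.0387, TSR1 at 0.28 ± 0.0479 and SRM at 0.26 ± 0.0496. Unfolded protein response genes had 10 rises and 4 falls among 21 (11 and 4 adjusted over the list alone; camera adjusted p = 0.0186, adjusted p = 0.0534 with an estimated correlation), with PDIA4 at 0.42 ± 0.0387, HYOU1 at 0.38 ± 0.0405 and CRELD2 at 0.67 ± 0.0773. Ribosomal protein genes had 21 rises and 4 falls among 61, also adjusted over the list alone (camera adjusted p = 0.0199, adjusted p = 0.532 with an estimated correlation). RPS16 was at 0.38 ± 0.0389, RPS19 at 0.44 ± 0.0469 and RPS28 at 0.60 ± 0.0672, and without shRNA replicate 3 the camera adjusted p of the list was 0.0894. Squamous differentiation genes had 8 rises and 4 falls among 21 (the same adjusted over the list alone), with a median of 0.23 but a mean of −0.39 (camera adjusted p = 0.0284, adjusted p = 0.111 with an estimated correlation and 0.0561 without scramble replicate 1). KRT13 rose by 0.77 (SE 0.04), PPL by 0.87 (SE 0.047) and S100P by 0.77 (SE 0.0754).

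A pair of further lists passed in TE10 narrowly. Mitochondrially encoded transcripts, which track RNA quality as well as mitochondrial content, took 5.23 ± 0.434% of gene reads with the shRNA and 6.0 ± 0.05% with the scramble. Of 13, 7 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0303, adjusted p = 0.513 with an estimated correlation), led by MT-ND5 (−0.42 ± 0.0346), MT-ND6 (−0.59 ± 0.0528) and MT-CO1 (−0.35 ± 0.0345). Imprinted genes had 7 falls and 3 rises among 14, the same adjusted over the list alone (camera adjusted p = 0.0461, adjusted p = 0.174 with an estimated correlation), with PEG10 at −1.49 ± 0.0787, GRB10 at −0.98 ± 0.0622 and PLAGL1 at −1.22 ± 0.144. Leaving out scramble replicate 1, shRNA replicate 1 or shRNA replicate 3 ended both calls, with camera adjusted p of 0.0561, 0.239 and 0.102 for the mitochondrial list and 0.0595, 0.0537 and 0.0894 for the imprinted list.

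Akt pathway components were not called as a list in TE10, with 5 rises and 10 falls among 28 (the same adjusted over the list alone; camera adjusted p = 0.216). Within it AKT1 rose by 0.17 (SE 0.0477) and AKT2 rose by 0.28 (SE 0.0469). The insulin receptor substrate gene IRS1 fell from 53.4 to 26.7 CPM, and on the log2 scale IRS2 fell by 0.96, PIK3R1 by 0.86 and PIK3CD by 0.87. INPP5D fell from 1.62 to 0.641 CPM (edgeR adjusted p = 0.0319). INSR rose by 0.63 and PDPK1 by 0.52. In Kyse410 IRS1 fell by 1.82, IRS2 by 0.89 and PIK3R1 by 0.80, INSR rose by 0.78 and PDPK1 fell by 0.16, while PIK3CD and INPP5D did not pass. These 7 genes were named after their values were seen. FOXO targets, which Akt signalling represses, had 3 rises and 7 falls among 18 (4 and 7 adjusted over the list alone; camera adjusted p = 0.164). DNA methylation genes had 8 rises and 3 falls among 19 (8 and 4 adjusted over the list alone; camera adjusted p = 0.229), with DNMT1 at 0.19 ± 0.0395. The lists of DNA replication (camera adjusted p = 0.051), immediate early genes (0.0582), replication histones (0.15), germline genes (0.193), p53 targets (0.193), ATF4 targets (0.404), apoptosis regulators (0.408), Wnt and Notch targets (0.79) and mitosis (0.978) were not called in TE10. The DNA replication list passed without scramble replicate 2, shRNA replicate 1 or shRNA replicate 2 (camera adjusted p = 0.0398, 0.0248 and 0.042). Immediate early genes passed without shRNA replicate 1 or 2 (0.0462 and 0.042) and germline genes without shRNA replicate 2 (0.042). Of 40 germline genes only 7 were tested, with 3 rises and 0 falls in TE10 (3 and 1 adjusted over the list alone), a median of 0.58 and a mean of 1.32. The result for this list therefore does not cover the members that were not tested.

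Of the 16 lists called in TE10, 9 were also called with an estimated correlation, at camera adjusted p of 0.000161 to 0.036. The labels do not state how many hairpin sequences were used, so effects of UHRF1 loss and off-target effects of a hairpin cannot be separated here.

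The same comparison was made in Kyse410, where the shRNA was accompanied by less RNA of inflammatory and early response genes and more RNA of cell cycle and epithelial genes. IL6 fell from 204.9 to 18.0 CPM, by 3.50 on the log2 scale (SE 0.0675), and JUN fell by 1.93 (SE 0.0374). The interferon-induced antiviral gene RSAD2 fell by 3.25 (SE 0.0997). The cyclin gene CCNE2 rose by 1.53 (SE 0.0917), and CDH1 rose by 0.79 (SE 0.0458). These changes passed the edgeR test at the adjusted threshold of 0.05.

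Of 16060 genes tested in Kyse410, 7921 passed an adjusted p of 0.05 in edgeR, 3627 higher and 4294 lower with the shRNA. A change of at least 2-fold was seen in 1145 of them, 749 higher and 396 lower. At a mean of at least 5 CPM in the line, the largest rises were in ALPG (log2 4.49 ± 0.101), NCCRP1 (4.48 ± 0.195), MPPED1 (3.61 ± 0.149), FRMD3 (3.48 ± 0.108), OTULINL (3.47 ± 0.131), CALHM3 (3.44 ± 0.173) and CSF3R, the receptor gene for granulocyte colony-stimulating factor (3.41 ± 0.142). The largest falls at this limit, after IL6, were in IL6-AS1 (−3.38 ± 0.12), RSAD2, the transcription factor gene CREB5 (−3.18 ± 0.105), the NKG2D ligand gene RAET1L (−2.70 ± 0.127), the endothelin gene EDN1 (−2.69 ± 0.142) and the transcription factor gene HLF (−2.67 ± 0.129). IL6-AS1 lies antisense to IL6 and its reads cannot be told apart from those of IL6 in these counts.

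Immediate early genes, which respond to growth factors and stress within minutes, had 19 falls and 1 rise among 21 in Kyse410 (20 and 1 adjusted over the list alone), with a median log2 fold change of −0.75 (camera adjusted p = 1.73e-36). EGR1 was at −1.10 ± 0.0335, and ATF3 was at −1.54 ± 0.0469. NF-kB targets and cytokine genes had 21 falls and 2 rises among 26 (23 and 2 adjusted over the list alone; camera adjusted p = 4.4e-25), with IL24 at −2.53 ± 0.0481 and TNFAIP3, an inhibitor of NF-kB, at −1.50 ± 0.0422. Interferon response genes had 24 falls and 4 rises among 39 (25 and 4 adjusted over the list alone; camera adjusted p = 1.67e-20), with IFIT2 at −2.36 ± 0.0442, IFIT3 at −1.99 ± 0.0604 and ISG15 at −1.28 ± 0.0392. Beside these groups, mitochondrially encoded transcripts took 3.90 ± 0.106% of gene reads with the shRNA and 2.38 ± 0.068% with the scramble (mean ± SD, n = 3 each). All 13 of them rose, also adjusted over the list alone (camera adjusted p = 1.59e-20, adjusted p = 0.028 with an estimated correlation of 0.671 between genes). MT-CO3 was at 0.88 ± 0.0319, MT-CO2 at 0.97 ± 0.0353 and MT-ATP6 at 1.01 ± 0.0442. The 10 most abundant genes took 7.08 ± 0.076% of gene reads with the shRNA and 4.68 ± 0.031% with the scramble.

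DNA replication genes had 35 rises and 0 falls among 39 in Kyse410 (36 and 0 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 1.51e-11). RRM2, a subunit of ribonucleotide reductase, was at 0.68 ± 0.0409 and PCNA, the replication clamp, at 0.74 ± 0.0537. Genes of G2 phase and mitosis had 23 rises and 1 fall among 34 (24 and 1 adjusted over the list alone; camera adjusted p = 1.19e-07), with MKI67 at 0.71 ± 0.0357, TOP2A at 0.72 ± 0.0424 and NUSAP1 at 0.76 ± 0.0482. Ribosome biogenesis genes went down, with 30 falls and 0 rises among 36 (31 and 0 adjusted over the list alone; camera adjusted p = 3.83e-14). ODC1 was at −0.83 ± 0.0387, RRP12 at −1.26 ± 0.0592 and DDX21 at −0.64 ± 0.0358. Ribosomal protein genes had 38 falls and 9 rises among 61 (39 and 9 adjusted over the list alone; camera adjusted p = 0.00118, adjusted p = 0.565 with an estimated correlation), with RPS23 at −0.46 ± 0.0356, RPS27A at −0.53 ± 0.0417 and RPS18 at −0.53 ± 0.0416. ATF4 targets had 17 rises and 9 falls among 30, the same adjusted over the list alone (camera adjusted p = 0.00118). The risers with the smallest adjusted p were PSAT1 (1.44 ± 0.056), MTHFD2 (1.07 ± 0.0446) and CTH (1.82 ± 0.0908), which encode enzymes of serine, one-carbon and cysteine metabolism, while the stress-induced transcription factor gene ATF3 fell by 1.54. ATF4 itself, named after its values were seen, fell by 0.47.

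Epithelial genes had 15 rises and 4 falls among 22 in Kyse410 (16 and 4 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 1.73e-09). KRT19 was at 1.34 ± 0.0452, KRT8 at 0.67 ± 0.037 and ST14 at 1.20 ± 0.0669. Mesenchymal genes had 9 falls and 4 rises among 17 (10 and 4 adjusted over the list alone), with a median of −0.48 (camera adjusted p = 0.000645). SPARC fell by 1.76 (SE 0.0735), FN1 by 1.17 (SE 0.0411), CDH2 by 1.04 (SE 0.122), SNAI2 by 0.88 (SE 0.051) and ZEB1 by 0.78 (SE 0.161). VIM rose by 0.32 (SE 0.0439) and SNAI1 by 0.95 (SE 0.116). Squamous differentiation genes had 12 rises and 3 falls among 21 (13 and 3 adjusted over the list alone; camera adjusted p = 0.000645), with EMP1 at 1.33 ± 0.0557, LCN2 at 1.45 ± 0.11 and the kallikrein gene KLK5 at 4.09 ± 0.365.

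Collagen, laminin and integrin genes had 19 falls and 10 rises among 31 in Kyse410 (20 and 10 adjusted over the list alone; camera adjusted p = 0.0203, adjusted p = 0.39 with an estimated correlation), with LAMB3 at −0.80 ± 0.0352, COL7A1 at −0.81 ± 0.0402 and COL4A1 at −0.73 ± 0.0462. TGF-beta targets had 12 falls and 11 rises among 25, the same adjusted over the list alone (camera adjusted p = 0.0351, adjusted p = 0.247 with an estimated correlation), with THBS1 at −1.90 ± 0.0553 and CCN1 at −1.11 ± 0.0365. Without shRNA replicate 2 both calls ended, at camera adjusted p of 0.0694 and 0.0966, and without shRNA replicate 3 the TGF-beta call ended at 0.0524.

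Akt pathway components were not called as a list in Kyse410 either, with 6 rises and 12 falls among 28 (the same adjusted over the list alone; camera adjusted p = 0.128). AKT1 rose by 0.46 (SE 0.0484). AKT2 was at 0.11 ± 0.0453 with an edgeR adjusted p of 0.0475, which became 0.0886 and 0.179 without scramble replicate 1 or 2, 0.11 and 0.129 without shRNA replicate 1 or 3, and 0.0651 without the filter on low counts. DNMT1 rose by 0.25 (SE 0.0395), and DNA methylation genes had 5 rises and 8 falls among 19 (the same adjusted over the list alone; camera adjusted p = 0.946). FOXO targets (camera adjusted p = 0.171), apoptosis regulators (0.145), Wnt and Notch targets (0.531), hypoxia and glycolysis (0.549), cholesterol (0.674), unfolded protein response (0.674), imprinted genes (0.674), p53 targets (0.674), matrix proteases (0.696), germline genes (0.711), basal squamous genes (0.764) and replication histones (0.983) were not called. In the 7 germline genes tested, of 40, 3 rose and 3 fell, with a median of −0.29 and a mean of 1.21. In imprinted genes the median was −0.28 and the mean 0.05.

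Of the 14 lists called in Kyse410, 11 were also called with an estimated correlation, at camera adjusted p of 0.000165 to 0.0328. As in TE10, the number of hairpin sequences is not stated, and the mitochondrial share moved with the groups.

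**Figure D2:**
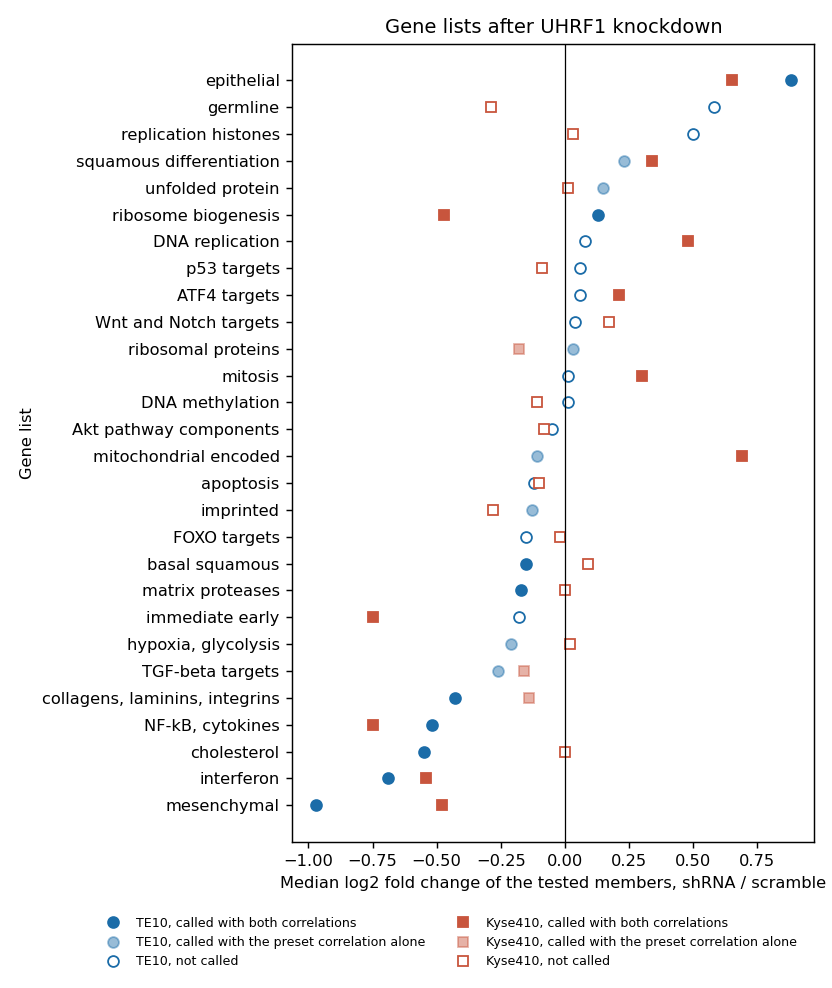
Median log2 fold change of the tested members of each gene list, shRNA over scramble (horizontal axis), for TE10 (circles) and Kyse410 (squares), with filled symbols for lists called by camera with both a preset and an estimated correlation between genes, pale symbols for the preset alone and open symbols for lists not called. Epithelial genes lie at 0.88 and 0.65 and interferon genes at −0.69 and −0.54 in TE10 and Kyse410, while ribosome biogenesis lies at 0.13 and −0.47.

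The responses of the lines were then set side by side. Among genes with a mean of at least 5 CPM in each line, those that rose most in both were ALPG, NCCRP1, MPPED1, ZNF114, B4GALNT1 and FRMD3. They rose by between 2.84 and 4.07 on the log2 scale in TE10 and between 3.24 and 4.49 in Kyse410. At the same limit, those that fell most in both were CREB5 (−2.48 in TE10 and −3.18 in Kyse410), SPARC (−3.83 and −1.76), MAP1B (−3.46 and −1.45), the activin antagonist gene FST (−1.84 and −1.48), IFIT2 (−1.56 and −2.36) and IFIT1 (−1.45 and −1.79). CDH1 rose and CDH2, FN1, SNAI2 and ZEB1 fell in both lines. Lists called in one direction in both with either correlation were epithelial genes upward, and mesenchymal, interferon and NF-kB genes downward.

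In all, 1117 genes were higher and 1451 lower with the shRNA in both lines, of 3019 and 3212 called in TE10 and 3627 and 4294 called in Kyse410. Without TE10 shRNA replicate 1 there were 1227 higher and 1136 lower. Independent lists of these sizes among 16060 genes would share 681.8 and 858.8 genes (one-sided Fisher's exact test, p = 2.99e-90 and 1.34e-142). Genes higher in TE10 and lower in Kyse410 numbered 689, and those lower in TE10 and higher in Kyse410 583, against 807.2 and 725.4 of independent lists. Of the 3840 genes called in both lines, 66.9% moved in the same direction. Across all genes tested the log2 fold changes of the lines correlated with Pearson's r = 0.356 and Spearman's rho = 0.214. Genes are not independent replicates, so these values describe the libraries at hand.

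**Figure D3:**
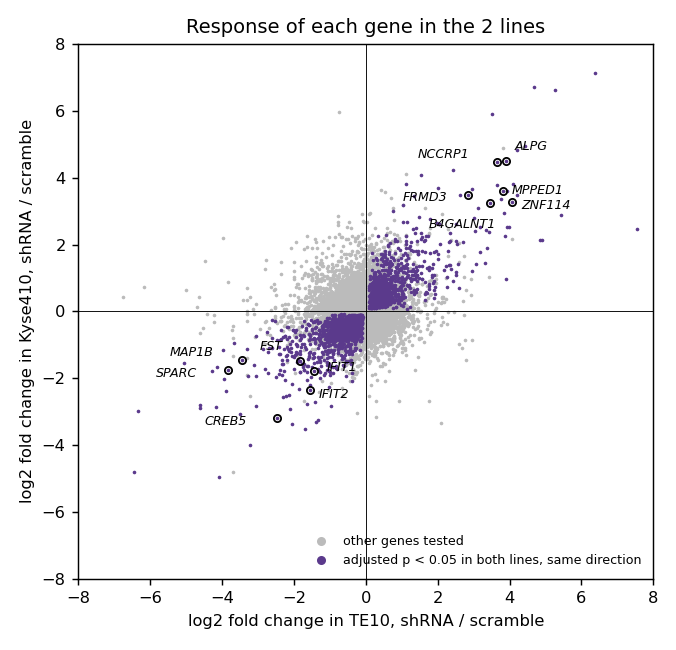
Log2 fold change with the UHRF1 shRNA in TE10 (horizontal axis) and in Kyse410 (vertical axis) for the 16060 genes tested, 1 point per gene. Purple points are the 2568 genes that passed an adjusted p of 0.05 in both lines in the same direction. Circled genes are the 6 with the largest shared rise and the 6 with the largest shared fall, at a mean of at least 5 CPM in each line.

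A direct test asked which responses differed between the lines, taking the Kyse410 fold change minus that of TE10. Stanniocalcin (STC1) fell by 1.82 in TE10 and rose by 1.37 in Kyse410, a log2 difference of 3.19 ± 0.0602. The cadherin gene FAT2 fell by 1.71 and rose by 1.86 (difference 3.57 ± 0.275), and NMNAT2 fell by 1.03 and rose by 2.21 (difference 3.24 ± 0.161). VIM was lower in TE10 and higher in Kyse410 with the shRNA, a difference of 1.57 ± 0.0576 (edgeR adjusted p = 2.85e-28). GDF15, a stress-induced cytokine gene, rose by 1.80 in TE10 and fell by 0.68 in Kyse410, a difference of −2.48 ± 0.0765.

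The test called 6240 of 16060 genes in edgeR at an adjusted p of 0.05, 3048 with a more positive response in Kyse410 and 3192 with a more positive response in TE10. Without Kyse410 shRNA replicate 2 these numbers were 3041 and 2717. Of the 1235 genes with a difference of at least 2-fold, 871 had the more positive response in Kyse410 and 364 in TE10. ADAM19 (3.18 ± 0.29) and KRT5 (3.29 ± 0.358) completed the 5 largest positive differences among genes with a mean of at least 5 CPM over the 12 libraries. KRT5 lay at 1.14 ± 0.568 CPM in the Kyse410 scramble libraries. At the same limit the largest negative differences besides GDF15 were in HLF (−4.44 ± 0.796), EDN1 (−2.98 ± 0.342), IL24 (−2.62 ± 0.252) and NEDD9 (−2.35 ± 0.278). These 4 genes fell in Kyse410 and were at most 3.03 CPM in either TE10 group, so the fitted value of HLF rests on 3 reads over the TE10 scramble libraries.

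Ribosome biogenesis genes differed most evenly, with 34 of 36 lower in the response of Kyse410 and 1 higher (the same adjusted over the list alone; camera adjusted p = 1.05e-22). Cholesterol genes had 18 positive and 0 negative differences among 25 (camera adjusted p = 4.88e-12), DNA replication 26 and 2 among 39 (6.49e-07), mitosis 24 and 0 among 34 (1.02e-07) and mitochondrially encoded transcripts 12 and 0 among 13 (4.83e-28). Mesenchymal genes had 8 positive and 2 negative among 17 (6.05e-05), matrix proteases 11 and 6 among 27 (0.000418) and immediate early genes 1 and 15 among 21 (9.73e-09). Adjusted over the list alone the counts were 18 and 0, 28 and 2, 26 and 0, 12 and 0, 9 and 2, 12 and 10 and 1 and 16 in the same order. Ribosome biogenesis and these 7 lists were also called with an estimated correlation, at camera adjusted p of 7.21e-05 to 0.0186. Mitochondrially encoded transcripts were then at 0.0156.

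A further 7 lists were called in the difference between lines with the preset correlation and lost with an estimated one. They were ribosomal proteins (9 positive and 36 negative of 61; camera adjusted p = 1.53e-07, adjusted p = 0.273 with an estimated correlation), hypoxia and glycolysis (16 and 2 of 30; 1.37e-06, then 0.056) and collagens, laminins and integrins (15 and 6 of 31; 3.94e-05, then 0.121). The others were basal squamous genes (8 and 6 of 22; 0.0158, then 0.056), ATF4 targets (14 and 8 of 30; 0.0355, then 0.121), NF-kB targets (3 and 12 of 26; 0.0355, then 0.0971) and imprinted genes (6 and 2 of 14; 0.0355, then 0.151). Adjusted over the list alone the counts of these 7 lists, in the same order, were 9 and 41, 18 and 3, 15 and 6, 9 and 6, 17 and 9, 3 and 12 and 7 and 2. The ATF4 call ended without TE10 shRNA replicate 2 (camera adjusted p = 0.0596) and the NF-kB call without TE10 shRNA replicate 1 or 2 (0.0667 and 0.051). The imprinted call ended without TE10 scramble replicate 1 or TE10 shRNA replicate 3 (0.056 and 0.0526). Interferon (camera adjusted p = 0.385), epithelial (0.217) and Akt pathway genes (0.696) were not called in the difference between lines.

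**Figure D4:**
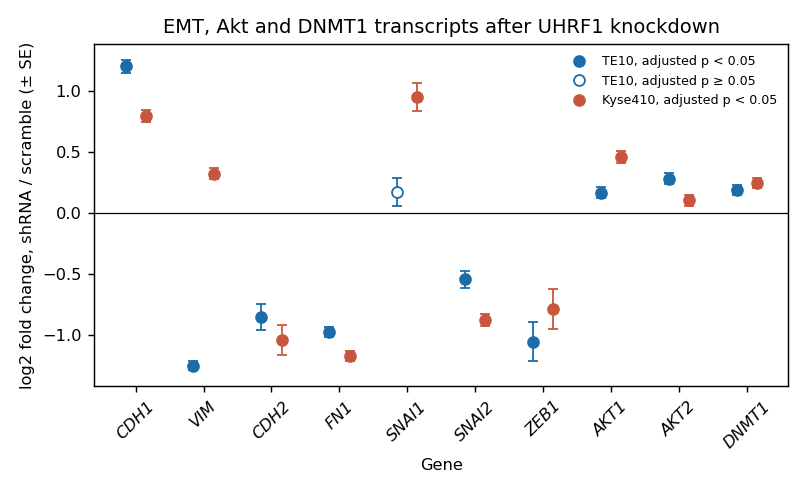
Log2 fold change, shRNA over scramble (vertical axis, ± SE), of EMT, Akt and DNMT1 transcripts in TE10 and Kyse410, from 3 libraries per group. Filled points passed an adjusted p of 0.05, and VIM lies below 0 in TE10 and at 0.32 in Kyse410.

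The scramble controls of the lines were compared to describe their starting states. Kyse410 had far more RNA of cytokine and early response genes, among them IL24 at 406.5 ± 4.71 CPM against 2.68 ± 0.52 CPM in TE10 (log2 difference 7.23 ± 0.0852), while TE10 had more RNA of the keratin genes KRT5 and KRT6A and of the chaperone gene HSPA8. KRT5 lay at 67.4 ± 1.06 CPM in TE10 and 1.14 ± 0.568 CPM in Kyse410 (−5.84 ± 0.154), the stress keratin gene KRT6A differed by −4.91 ± 0.0658, and HSPA8 lay at 3427 ± 46.5 and 63.7 ± 3.26 CPM (−5.75 ± 0.0428). CDH1 was higher in Kyse410 (1.13 ± 0.055) and VIM (−2.92 ± 0.0409), CDH2 (−0.88 ± 0.102), ZEB1 (−0.65 ± 0.142) and UHRF1 (−0.85 ± 0.0497) were lower.

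In edgeR 11839 of 16060 genes passed an adjusted p of 0.05 between the scramble controls, 5886 higher in Kyse410 and 5953 higher in TE10. At least 2-fold apart were 4524, of which 2543 were higher in Kyse410 and 1981 in TE10. IL20 differed by 7.56 ± 0.245 and the aldo-keto reductase gene AKR1C1 by −4.94 ± 0.252 on the log2 scale. AKR1C1 belongs to a family of similar genes and its level is uncertain. HLF had 1062 reads in the Kyse410 and 3 in the TE10 scramble libraries, a ratio of 277 with a 95% counting interval of 94.7 to 1350, and KRTAP5-1 had 375 and 1, a ratio of 294 (52.4 to 11600).

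Of the gene lists, immediate early genes were higher in Kyse410 for 20 of 21 members and lower for 0, with a median log2 difference of 3.70 (camera adjusted p = 7.85e-68). NF-kB targets and cytokines were higher for 23 of 26 and lower for 0 (1.32e-26), ATF4 targets higher for 26 and lower for 2 of 30 (1.94e-24), TGF-beta targets 18 and 5 of 25 (4.36e-08), FOXO targets 12 and 2 of 18 (1.28e-05) and p53 targets 15 and 7 of 25 (2.49e-05). Lower in Kyse410 were mitochondrially encoded transcripts for 13 of 13 (3.25e-33), mitosis for 32 of 34 (5.15e-16), cholesterol for 20 of 25 (1.2e-15), ribosome biogenesis for 29 of 36 (2.99e-08), DNA replication for 35 of 39 (4.36e-08) and unfolded protein response genes for 15 of 21 (3.5e-06). The counts of these 12 lists were the same adjusted over the list alone. Each was also called with an estimated correlation, at camera adjusted p of 0.000356 to 0.00695, with mitochondrially encoded transcripts at 0.00688. Collagens, laminins and integrins (17 higher and 6 lower of 31; camera adjusted p = 0.00036, adjusted p = 0.171 with an estimated correlation), apoptosis regulators (16 and 8 of 30; 0.00665, then 0.072) and ribosomal proteins (7 and 47 of 61; 1.67e-06, then 0.303) were called with the preset correlation. Basal squamous genes were not called (8 higher and 12 lower of 22, the same adjusted over the list alone; camera adjusted p = 0.912). Squamous differentiation genes were not called (10 higher and 9 lower of 21; camera adjusted p = 0.052), but passed without Kyse410 scramble replicate 1 or 2 (0.0475 and 0.0431). Their median was 0.21 and their mean −0.37. With 1 line against 1 line, these differences describe the TE10 and Kyse410 scramble libraries and carry no information on other lines.

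Markers of cells that such cultures should lack were also measured. Of 16 blood and immune cell markers 1 was expressed enough to test, CSF1R, and the highest level of any in a library was 8.78 CPM. Of 15 fibroblast and endothelial markers 4 were tested, CDH5, COL1A1, ENG and PDGFRB, and the highest level of any in a library was 159 CPM. CDH5, the endothelial cadherin gene, rose in Kyse410 with the shRNA from 24.7 ± 0.17 to 95.7 ± 7.63 CPM and in TE10 from 9.13 ± 1.75 to 14.1 ± 1.53 CPM. COL1A1 rose in Kyse410 from 114 ± 6.04 to 154 ± 7.02 CPM and in TE10 from 42.8 ± 0.865 to 51.2 ± 3.51 CPM. ENG, an endothelial coreceptor of TGF-beta, rose in Kyse410 from 75.0 ± 0.76 to 112 ± 2.74 CPM and fell in TE10 from 93.1 ± 4.77 to 63.3 ± 6.37 CPM. PDGFRB fell in Kyse410 from 5.81 ± 0.473 to 3.47 ± 0.185 CPM and in TE10 from 3.6 ± 1.3 to 0.736 ± 0.288 CPM. All 8 of these changes passed the edgeR test at the adjusted threshold of 0.05. CSF1R did not pass in either line (edgeR adjusted p = 0.297 in TE10 and 0.195 in Kyse410). These 5 genes were named after their values were seen. Neither list had the 5 tested members needed for camera.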

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

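The tests of the scramble construct, of handling, of mitochondrial transcripts, of IL6-AS1 and of other splits of the libraries, except the split test of genes shared by both lines, were chosen after the result was seen. Groups of 3 libraries are too small for a search for outlying libraries. The 6240 genes and the lists and genes of the 2 paragraphs after them stood out because the test of the difference between the lines, Kyse410 minus TE10, passed an adjusted p of 0.05 in edgeR or camera. Results on 1 line alone or on both lines together were taken up apart from that test.

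The response to the UHRF1 shRNA differed between the lines in 6240 genes. Of 100 pairs of splits of the libraries, 10 within each line, 1 gave a count as large, the real one, and the highest other was 2222. For the 2568 genes changed the same way in both lines, 1 of 100 gave a count as large and the highest other was 0. The other splits mix shRNA and scramble libraries in 1 line or both, which puts the difference between these groups into the spread and left 0 calls in the mixed line. They therefore do not show what chance would give, and both counts stay open on it. In TE10 (6231 genes, highest other split 0), Kyse410 (7921, 0) and the scramble controls (11839, 0), 10 splits are too few for a share under 0.05.

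Among the gene lists the median log2 difference was 1.04 for mitochondrially encoded transcripts, 0.75 for mesenchymal genes, 0.60 for cholesterol, 0.35 for DNA replication, 0.30 for mitosis, 0.27 for hypoxia and glycolysis, 0.27 for imprinted genes, 0.23 for ATF4 targets, 0.22 for collagens, laminins and integrins, 0.22 for matrix proteases and 0.15 for basal squamous genes. It was −0.66 for immediate early genes, −0.54 for ribosome biogenesis, −0.24 for NF-kB targets and −0.22 for ribosomal proteins. The calls of the imprinted, ATF4 and NF-kB lists lay near the threshold, each at a camera adjusted p of 0.0355, and ended without certain libraries. Without TE10 scramble replicate 1 or shRNA replicate 3 the imprinted list had a camera adjusted p of 0.056 or 0.0526. Without TE10 shRNA replicate 2 the ATF4 list had 0.0596, and without TE10 shRNA replicate 1 or 2 the NF-kB list had 0.0667 or 0.051.

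Among genes set in advance the log2 difference was 1.57 for VIM, 0.78 for SNAI1 and 0.29 for AKT1, and −0.41 for CDH1, −0.33 for SNAI2, −0.20 for FN1 and −0.18 for AKT2. At a mean of at least 5 CPM over the 12 libraries, the largest differences were in FAT2 (3.57), KRT5 (3.29), NMNAT2 (3.24), STC1 (3.19) and ADAM19 (3.18), and in HLF (−4.44), EDN1 (−2.98), IL24 (−2.62), GDF15 (−2.48) and NEDD9 (−2.35). Among genes that moved the same way in both lines the size differed for SPARC (2.07), MAP1B (2.01), FRMD3 (0.64), ALPG (0.59), IFIT1 (−0.33), CREB5 (−0.70) and IFIT2 (−0.80).

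Interferon response genes were lower with the shRNA in both lines. Their median log2 fold change after a correction for GC content and transcript length was −0.65 in TE10 (95% bootstrap interval −0.94 to −0.56, −0.69 before) and −0.53 in Kyse410 (−1.03 to −0.33, −0.54 before), which argues against that bias as the whole cause. A response of the control cells to the scramble construct or its culture cannot be told apart from an effect of the UHRF1 shRNA, since 0 libraries came from cells without a construct. Loss of UHRF1, the biological difference the design names, stays open and was not tested separately.

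In Kyse410 immediate early genes were lower and mitochondrially encoded transcripts higher with the shRNA. The median of the immediate early list was −0.82 after the correction for GC content and length (95% bootstrap interval −1.11 to −0.59, −0.75 before), against that bias as the whole cause. The rise in mitochondrial share would shift all other genes by −0.02 on the log2 scale, outside the interval of the list's median before correction (−1.1 to −0.5), which argues against a larger share of the counts as the whole cause. Handling or culture state that coincides with the groups cannot be told apart from an effect of the shRNA, since the labels give 0 dates of culture or handling.

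IL6-AS1 was lower with the shRNA in Kyse410 together with IL6. In the Kyse410 scramble libraries the IL6-AS1 count averaged 1.16 times that expected of IL6 reads on the exon bases the genes share. The mean minus and plus the SD over these libraries gave 1.12 and 1.20, as reads of IL6 counted for its antisense partner would. No biological explanation was tested for IL6-AS1.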

How the results depend on the processing

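Leaving out mitochondrial transcripts was chosen after the data were seen. No named gene or list that was called reversed its direction. Counts of called genes stayed within 1.5 times under each alternative except an absolute log2 fold change of at least 1, which by its construction left 971 genes in TE10, 1145 in Kyse410, 1235 for the difference and 4524 between scramble controls. Leaving out 1 library at a time gave 5442 to 5830 genes in TE10, 7140 to 7426 in Kyse410, 5758 to 6134 for the difference between lines, 11396 to 11527 between scramble controls and 2306 to 2474 in both lines. UHRF1 then stayed between −1.08 and −0.99 in TE10 and between −1.25 and −1.21 in Kyse410. The DESeq2 test called 5523, 7029, 5501, 11298 and 2217 genes in the same order of comparisons, and without mitochondrial transcripts edgeR called 6218, 7880, 6248, 11815 and 2571. The balance of higher and lower calls did turn. In TE10 it went from 3019 and 3212 to 3375 and 2984 with DESeq2 size factors, 2922 and 2601 with the DESeq2 test, 3437 and 2863 with the 1 CPM filter and 3075 and 2564 without shRNA replicate 1. For both lines it went from 1117 and 1451 to 1318 and 1251 with the 1 CPM filter and 1227 and 1136 without TE10 shRNA replicate 1. For the difference it went from 3048 and 3192 to 3078 and 2740 with no filter and 3041 and 2717 without Kyse410 shRNA replicate 2. Between scramble controls it went from 5886 and 5953 to 6086 and 5742 with size factors, 5792 and 5506 with the DESeq2 test, 6142 and 6057 with no filter and 5894 and 5878 with the scramble libraries alone. At an absolute log2 fold change of at least 1 it went from 3627 and 4294 to 749 and 396 in Kyse410, to 871 and 364 for the difference and to 2543 and 1981 between scramble controls. With DESeq2 size factors the median log2 fold change of all genes moved from 0.001 to 0.024 in TE10 and from −0.002 to 0.028 between scramble controls. The split of small changes into higher and lower thus depends on the scaling there. The cause of the other turns was not tested.

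No clear pairing of the samples by replicate number was seen. Deviations of shRNA and scramble libraries of the same number correlated across genes at 0.022, −0.02 and 0.039 in TE10 and at 0.064, 0.12 and −0.027 in Kyse410. Libraries of other numbers in Kyse410 lay between −0.17 and 0.111. Such weak correlations cannot exclude that libraries of the same number were cultured or prepared together. With the number as a block edgeR called 6346, 7993, 6368, 11837 and 2641 genes.

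For named genes 2158 of 2163 fits kept direction and side of the threshold. The exceptions were of AKT2 in Kyse410, with an adjusted p of 0.0651 without the filter on low counts and 0.0886 to 0.179 without scramble replicate 1 or 2 or shRNA replicate 1 or 3. For lists 1599 of 1704 fits did so. TGF-beta targets in Kyse410 lost their call with the 1 CPM filter (0.0616), in the line alone (0.0618) and with no filter (0.383), collagens, laminins and integrins in Kyse410 in the line alone (0.0557), and basal squamous genes in the difference with no filter (0.0534). In TE10 squamous differentiation lost it with no filter (0.104), mitochondrial transcripts with the 1 CPM filter (0.0627) and size factors (0.0519), and imprinted genes with these (0.0627 and 0.0519), in the line alone (0.0771), with the block (0.0557) and without mitochondrial transcripts (0.053). Calls gained with no filter were DNA replication (0.00763), immediate early (0.00237), germline (0.00292) and FOXO lists (0.0414) in TE10 and epithelial genes between scramble controls (0.0433). In TE10 DNA replication also passed with the 1 CPM filter (0.0371) and size factors (0.0361). Between scramble controls squamous differentiation passed with the 1 CPM filter (0.0131), the block (0.0495) and the scramble libraries alone (0.0214), and hypoxia and mesenchymal genes passed with the scramble libraries alone (0.0446 each). An estimated correlation ended 20 calls, and fry, which does not compare a list with other genes, added 36. The cause was not tested for these lists. In simulated data with 3 libraries per group 64% of genes changed 1.5-fold were called in TE10 and 70% in Kyse410, and depth was not varied.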

Other observations

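The lists in the next 2 paragraphs and their tests were chosen after gene values were seen. The silent gene tests in the last paragraph were set before their result was seen. Targets of NRF2, the transcription factor of the oxidative stress response, were higher with the shRNA in TE10, where 22 of 25 rose and 0 fell, likewise adjusted over the list alone (median log2 fold change 0.86, camera adjusted p = 2.05e-26, 0.000242 with an estimated correlation). TXNRD1 rose by 1.15, FTL by 1.22, GPX2 by 2.01 and HMOX1 by 1.12 on the log2 scale. In Kyse410 16 rose and 3 fell (median 0.49, camera adjusted p = 0.00132, adjusted p = 0.0929 with an estimated correlation). The difference between the lines had a median of −0.16 (camera adjusted p = 0.000842, adjusted p = 0.0716 with an estimated correlation).

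Heat shock genes were lower in Kyse410 than in TE10 among scramble controls for 20 of 22, and higher for 0 (median −2.08, camera adjusted p = 5.01e-49, 3.37e-06 with an estimated correlation). HSPA8 lay at 3427 CPM in TE10 and 63.7 in Kyse410, HSP90AA1 at 2804 and 276 CPM and HSPA1A at 355 and 16.3 CPM. With the shRNA 14 rose and 1 fell in TE10 (camera adjusted p = 4.83e-05, 0.00378 with an estimated correlation), while in Kyse410 5 rose and 10 fell and the list was not called (0.329). The difference between the lines was called, with 5 genes higher and 13 lower in Kyse410 minus TE10 (camera adjusted p = 0.000311, 0.00983 with an estimated correlation). MHC class I genes fell for 10 of 15 in TE10 and rose for 0 (camera adjusted p = 0.002, adjusted p = 0.0557 with an estimated correlation) and were not called in Kyse410 (0.329), and the difference between the lines was not called (0.142). Of 28 trophoblast genes 9 were tested, and camera called them upward in TE10 (5 rose and 3 fell, median 1.0 and mean −0.13, adjusted p = 5.71e-06) and in Kyse410 (4 rose and 2 fell, adjusted p = 1.37e-05), also with an estimated correlation (0.00461 and 0.0158). The hormone subunit gene CGA rose by 1.03 in TE10, from a low level of 1.88 to 3.93 CPM, and by 2.68 in Kyse410. Against the call, INSL4 was at −4.2 in TE10 and −2.9 in Kyse410, and PLAC1 at −6.17 in TE10, all from low levels. ALPP, whose rise is given above, is among the 9, so the call rests in part on values already seen. Of 20 pluripotency genes 4 were tested, too few for camera, and ZFP42 rose by 3.19 and 1.77.

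A hypothesis was that loss of UHRF1, which maintains DNA methylation, frees genes that are silent in the control cells. The loss was partial, since 48.1% of the UHRF1 transcript remained in TE10 and 42.9% in Kyse410. Libraries were thinned at random, in a single draw, to 7857662 gene reads in TE10. There 15 genes had 0 counts in the scramble libraries and at least 10 over the shRNA libraries, and 18 the other way round (exact binomial test, one-sided, p = 0.757). No surplus of genes switched on was seen in TE10, though so few genes cannot exclude a modest one. Some of the 15, such as GAGE12G, named after its values were seen, had all their reads in a single shRNA library. Genes with a few control reads lie outside this test. In Kyse410, thinned to 8794930 gene reads, 24 were switched on and 9 off (exact binomial test, one-sided, p = 0.00677). That surplus goes the way of the hypothesis, but the test takes an even split as its reference. Among called genes changed at least 2-fold, rises also outnumbered falls in Kyse410 (749 and 396). In TE10 falls outnumbered rises (343 and 628). The test therefore cannot tell a release of silent genes from the general balance of changes in a line. The difference between the lines in this respect was not tested, and DNA methylation was not measured in these libraries. In both lines 3 genes were switched on and 0 off. They were PNMA5, MARCOL and 1 pseudogene without a symbol, named after their values were seen. Some genes counted as switched in Kyse410 had a read on the silent side before the thinning. Examples, also named after their values were seen, were SPINK1 among those on and C17orf49 among those off.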
